A study of Mus musculus with 2 samples.

How the data were processed

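RNA-seq was done on polyadenylated RNA from 2 samples of mouse bone marrow-derived macrophages, biological replicates 1 and 2 of a single treatment group (30 min, 100 ng/ml). Per the labels the starting amount was 1 µg. The labels disagree on the ligand, lipid A in the description and lipoprotein A in the source and treatment fields. Per the deposited text files the values were made on assembly mm10 with annotation M21. The quantification tools and their versions are not given in the sources used here. The column layout of the main files is the one RSEM writes, and that of a second set is the one kallisto writes.

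Each library had 3 deposited tables: a gene table and a transcript table derived from a transcriptome alignment, and a second transcript table derived from the reads and an index. Per the file headers the gene table gave expected counts, TPM, FPKM and a posterior mean TPM. Expected counts in the deposited tables were estimated reads per gene or transcript, whole for many genes and fractional for others, and not normalized. The deposited TPM values summed to the same fixed total over all entries of a table up to rounding, and the deposited FPKM values were proportional to them. The other deposited columns in another unit were the bounds of a credibility interval of TPM, whose level is not stated, and they were not used. The second transcript table gave, per the file headers, estimated counts and TPM per transcript, which were summed per gene and used as an alternative only.

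All 55536 gene identifiers of the tables were found in the annotation, with symbol, biotype and coordinates, and 55450 were also in the table of gene names. The tables also held entries that name no gene, namely 26248 numeric identifiers and 96 ERCC spike-ins, all at 0, and phiX with 0.0891% and 0.0698% of the counts of replicates 1 and 2. These were left out of counts and gene lists, and TPM was not rescaled. Depth over genes was 37784941 and 51904470 expected counts, so that a gene with 0 counts may have up to 3 counts, or 0.0794 and 0.0578 CPM. Intervals for shares are 95% Wilson intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Reads of genes with near-identical copies, such as Ifit3, Fth1, Ftl1, Eef1a1, Gapdh and mitochondrially encoded genes, were assigned by the quantification tools and their levels carry that uncertainty.

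The choices in this paragraph and the next were made before the data were examined. The 28 gene lists were the 4 response lists (immediate early, early inflammatory, delayed inflammatory, interferon response), signal feedback, TLR4 pathway, NF-kB subunits, other pattern receptors, macrophage identity, lysosome, alternative activation, cell cycle, housekeeping, glycolysis, cholesterol and lipid, mitochondrially encoded, and markers of T cells, B cells, NK cells, neutrophils, dendritic cells, monocytes, erythroid cells, mast cells and basophils, megakaryocytes, stromal cells, endothelial cells and osteoclasts. All 418 members were matched by symbol, and 1 symbol, Aldoa, with 2 identifiers was taken as the identifier with the most reads, a choice made once the identifiers were seen. Genes were named by rule: the 20 of highest mean TPM, in each list the 4 of highest mean TPM, the members below 1 TPM in both libraries and 30 genes fixed by name, the 10 with the largest ratio between libraries among genes with a mean of 10 TPM and 50 counts in at least 1 library, and for transcripts the genes at 10 TPM or more whose second transcript took 20% or more in both libraries, at most 8. The exceptions, singled out after their values were seen, were biotype classes, Tlr2, genes of the second neutrophil list and mitochondrial genes named beside their copies.

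A gene counted as detected at 1 TPM or more in both libraries. Levels were compared as log2(TPM + 1). With 2 libraries in a single group, no test between conditions was possible and no p-value between groups is given. The 4 response lists were compared within the libraries by a two-sided permutation test over genes with 100000 resamples of the difference in medians of mean log2(TPM + 1), whose smallest possible p is 2e-05, with Benjamini-Hochberg adjustment over 6 pairs. For tests on counts, expected counts were rounded first. The biological coefficient of variation was the square root of the common dispersion in edgeR, with an intercept-only design, TMM scaling and filterByExpr. An exact binomial test per gene, adjusted by Benjamini-Hochberg at 0.05, asked whether the 2 libraries differed beyond sampling noise. The shift of a list between libraries was its median log2 ratio of replicate 2 to replicate 1, placed among 10000 random lists of the same size matched on mean expression within a window of 100 ranks, a width not fixed beforehand. Its percentile is not a p-value, since genes of a list move together.

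Alternatives were, for detection, limits of 0.5 and 5 TPM, the mean of both libraries, FPKM, 10 counts and the second quantification. For the correlation they were a pseudocount of 0.1 TPM, no filter, a mean of 10 TPM and TMM-normalized CPM. For the tests on counts they were DESeq2 size factors, total counts and no filter. For the pairs of lists they were a pseudocount of 0.1 TPM, members at 1 TPM or more only, TMM-normalized CPM and means in place of medians. For the share of the top 20 genes they were TPM and leaving out mitochondrially encoded genes, and for list shifts TMM-normalized CPM (prior count 1), DESeq2 size factors and a pseudocount of 0.1 TPM. Levels and transcript shares were also taken from the second quantification, and levels from the posterior mean. Each replicate was left out in turn where a value remained. Further alternatives for list shifts were chosen after seeing the data. They were members at 1 TPM or more, TPM rescaled without ribosomal and mitochondrial genes and copies, and protein-coding transcripts only. The second quantification was another, as was matching on expression, GC content and transcript length over the 200 nearest genes.

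The code was tested on simulated data. Counts of 12266 genes simulated with a biological coefficient of variation of 0.2 gave back 0.197. With sampling noise alone, 96% of genes changed 1.5-fold, 98% changed 2-fold and 100% changed 4-fold or 8-fold were called, 50 genes each, against 0.0829% of 12066 unchanged genes. Of 200 pairs of random lists 4.5% had a permutation p below 0.05, against 100% of 50 pairs shifted by 2 SD, and 4% of 200 random lists lay outside the central 95%, against 100% of 50 lists shifted by 0.5 on the log2 scale. The work used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.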

Results

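The series held 2 RNA-seq libraries of polyadenylated RNA from macrophages that had been grown from the bone marrow of C57BL/6J mice and treated for 30 min with a bacterial ligand at 100 ng/ml. The free-text label calls the ligand lipid A, the membrane anchor of lipopolysaccharide that the receptor TLR4 recognises. The source and treatment labels call it lipoprotein A and class it as a protein, and nothing in the labels settles which was used. Both libraries belonged to the same group, biological replicates 1 and 2, with separate biosample records under the same donor record. There were no untreated samples, so the levels below describe macrophages 30 min into treatment and cannot show that any gene was induced. Replicate 1 held 37784941 expected counts over annotated genes and replicate 2 held 51904470. A mean level is given below as TPM, the length-scaled relative abundance of a transcript, ± SD with n = 2 libraries. Levels given in pairs are those of replicate 1 and then replicate 2, and coordinates are on mm10 (GRCm38).

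Genes that mark macrophages and their lysosomes were among the most abundant in both libraries. Of the 30 genes of the macrophage identity list, 29 were at 1 TPM or more in both libraries and 21 at 100 TPM or more, with a list median of 288 ± 22.4 TPM. Lyz2 (ENSMUSG00000069516.8, chromosome 10, 117277331 to 117282321), which encodes lysozyme, was at 19017 ± 4398 TPM, and Apoe, the lipid carrier apolipoprotein E, at 11947 ± 933 TPM. Adgre1 (ENSMUSG00000004730.15, chromosome 17, 57358691 to 57483527), which encodes the surface marker F4/80, was at 755 ± 63.2 TPM. Csf1r (ENSMUSG00000024621.16, chromosome 18, 61100598 to 61132149), the receptor for the growth factor on which macrophages depend, was at 823 ± 83.5 TPM. Gpnmb, a glycoprotein of the lysosome and cell surface, was at 16037 ± 1428 TPM, but at 8106 TPM in the second deposited quantification. The fractalkine receptor Cx3cr1, with 53 and 43 counts, was the member below 1 TPM in both libraries. All 23 genes of the lysosome list were at 10 TPM or more in both libraries, with a median of 778 ± 4.79 TPM. The lysosomal protein prosaposin, Psap, was at 15107 ± 1278 TPM, and the proteases Ctsd and Ctsb were at 15027 ± 1807 and 12085 ± 1506 TPM.

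In all, 10658 genes were at 1 TPM or more in both libraries, 9983 of them protein-coding, and 97 genes were at 1000 TPM or more. The iron storage genes Fth1 and Ftl1 stood at 23751 ± 3631 and 23151 ± 32.3 TPM. Also among the 20 genes of highest mean TPM were Selenop at 7274 ± 2157 TPM, Tmsb4x at 5336 ± 2.37 TPM and Lgals3 at 4967 ± 851 TPM. The 20 genes with the most counts took 28.7% and 23.4% of the counts, a mean of 26.1% ± 3.71 (SD, n = 2). They include a ribosomal RNA gene, described next, that alone took 10.9% and 5.05%. The higher share in replicate 1 therefore does not show that its mRNA was more concentrated. The gene of highest TPM was CT010467.1 (ENSMUSG00000106106.2, chromosome 17, 39846353 to 39848827), annotated as ribosomal RNA. It took 10.9% of the counts of replicate 1 (95% Wilson interval 10.9% to 11.0%) and 5.05% of those of replicate 2 (5.04% to 5.05%), a difference far outside counting error. The TPM of mt-Atp8, at 42932 ± 1606, rested on an effective length of 13.9 and 12.2 bases, and in the second quantification the gene was at 9918 TPM. The unprocessed pseudogenes Gm28437, Gm28661, Gm10925 and Gm28438, which lie side by side on chromosome 1, were at 10297 ± 2043, 9829 ± 3174, 8581 ± 475 and 6657 ± 1776 TPM. Their sequence is shared with genes of the mitochondrial genome, and in the second quantification Gm10925 was at 126 TPM and Gm28438 at 2646 TPM.

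Markers of most other cell types were low or undetected, apart from single members. Monocyte genes were all detected at low levels, and 5 of 12 neutrophil markers were at 1 TPM or more in both libraries. Of 9 T cell genes, 6 were below 1 TPM in both libraries, Cd8a had 0 counts, and Cd28 and Il7r stood apart at 205 ± 13.1 and 97.9 ± 20.2 TPM. Of 9 B cell genes, 7 were below 1 TPM, Rag1 had 0 counts, and Cd22, a lectin, was at 23.8 ± 1.12 TPM. None of the 7 NK cell genes and none of the 10 mast and basophil genes reached 1 TPM in both libraries, and all 12 stromal genes were below 1 TPM in both. Of 9 erythroid genes, 8 were below 1 TPM in both libraries, among them the globin genes Hba-a1, Hbb-bs and Hbb-bt at 0 counts. With 0 counts, the limit of 3 counts corresponds to 0.0794 and 0.0578 CPM in the 2 libraries. Dendritic cell genes had a list median of 0.65 ± 0.37 TPM, with Itgax at 5.50 ± 2.28 TPM and Batf3 at 4.47 and 4.48 TPM. Osteoclast genes had a list median of 0.80 ± 0.07 TPM, with the integrin gene Itgb3 highest at 9.54 ± 2.17 TPM. Endothelial genes had a median of 0.30 ± 0.09 TPM, although Vwf and Kdr were at 20.0 ± 12.1 and 8.47 ± 4.74 TPM. All 4 monocyte genes were at 1 TPM or more in both libraries, with a median of 8.23 ± 0.72 TPM. Ly6c2 was at 15.7 and 8.38 TPM and Plac8, which went the other way, at 7.65 and 14.9 TPM. Among megakaryocyte genes the chemokine gene Pf4 was at 962 and 250 TPM, Ppbp at 9.05 and 1.96 TPM, and the other 4 were below 1 TPM. Neutrophil markers took 0.0113% of the counts of replicate 1 (Wilson interval 0.0110% to 0.0117%) and 0.00273% of those of replicate 2 (0.00259% to 0.00288%). The most abundant were S100a9 at 183 and 37.1 TPM and S100a8 at 124 and 18.1 TPM, while Mpo, Cxcr2, Retnlg and Ly6g were below 1 TPM in both.

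Lists of genes that are known to respond to TLR ligands with different speed were compared within these libraries. Immediate early genes, whose transcription needs no new protein, were abundant: 20 of 25 were at 1 TPM or more in both libraries, with a median of 83.4 ± 14.4 TPM. The transcription factor genes Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273) and Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984) were at 1016 ± 275 and 659 ± 58.0 TPM. Junb was at 640 ± 153 TPM, Atf3 at 572 ± 90.1 TPM and Ier3 at 368 ± 33.1 TPM, while Fosl1 had 0 counts and Hes1 had 2 and 0. Of 29 signal feedback genes, mostly regulators of NF-kB and MAP kinase signals, 27 were at 1 TPM or more, with a median of 19.6 ± 4.24 TPM. Among them Zfp36, which encodes a protein that destabilises cytokine mRNA, was at 1224 ± 188 TPM, and the phosphatase gene Dusp1 at 627 ± 73.3 TPM. The NF-kB inhibitor gene Nfkbia (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647) was at 862 ± 448 TPM and Tnfaip3, which encodes A20, at 252 ± 148 TPM.

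Early inflammatory genes were abundant too. Of 20, 17 were at 1 TPM or more in both libraries, with a median of 130 ± 85.2 TPM. The cytokine gene Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) was at 1273 ± 591 TPM and the chemokine gene Cxcl2 (ENSMUSG00000058427.10, chromosome 5, 90903871 to 90905938) at 697 ± 365 TPM. Ccl3 was at 646 ± 117 TPM and Il1b at 440 ± 416 TPM, whereas Cxcl3, Edn1 and Lif were below 1 TPM in both libraries. Delayed inflammatory genes, which in such cells need new protein or chromatin remodelling, were low: 9 of 20 were at 1 TPM or more in both libraries, with a median of 1.28 ± 0.60 TPM. Il6 had 10 and 121 counts (0.46 and 3.96 TPM), Il12b had 41 and 279 (3.02 ± 2.81 TPM), Nos2 had 42 and 115 (0.43 and 0.83 TPM) and Csf3 had 0 in both. The most abundant of the delayed list were Ccl5 at 103 ± 40.9 TPM, Ebi3 at 59.9 ± 15.0 TPM and Saa3 at 52.0 ± 2.81 TPM. Of 26 interferon response genes, 23 were at 1 TPM or more in both libraries, with a median of 60.7 ± 39.2 TPM. Irf1 was at 307 ± 221 TPM, Cxcl10 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889) at 203 ± 212 TPM and Isg15 at 137 ± 99.5 TPM. The interferon gene Ifnb1 itself had 1 count in replicate 1 and 59 in replicate 2.

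**Figure D1:**
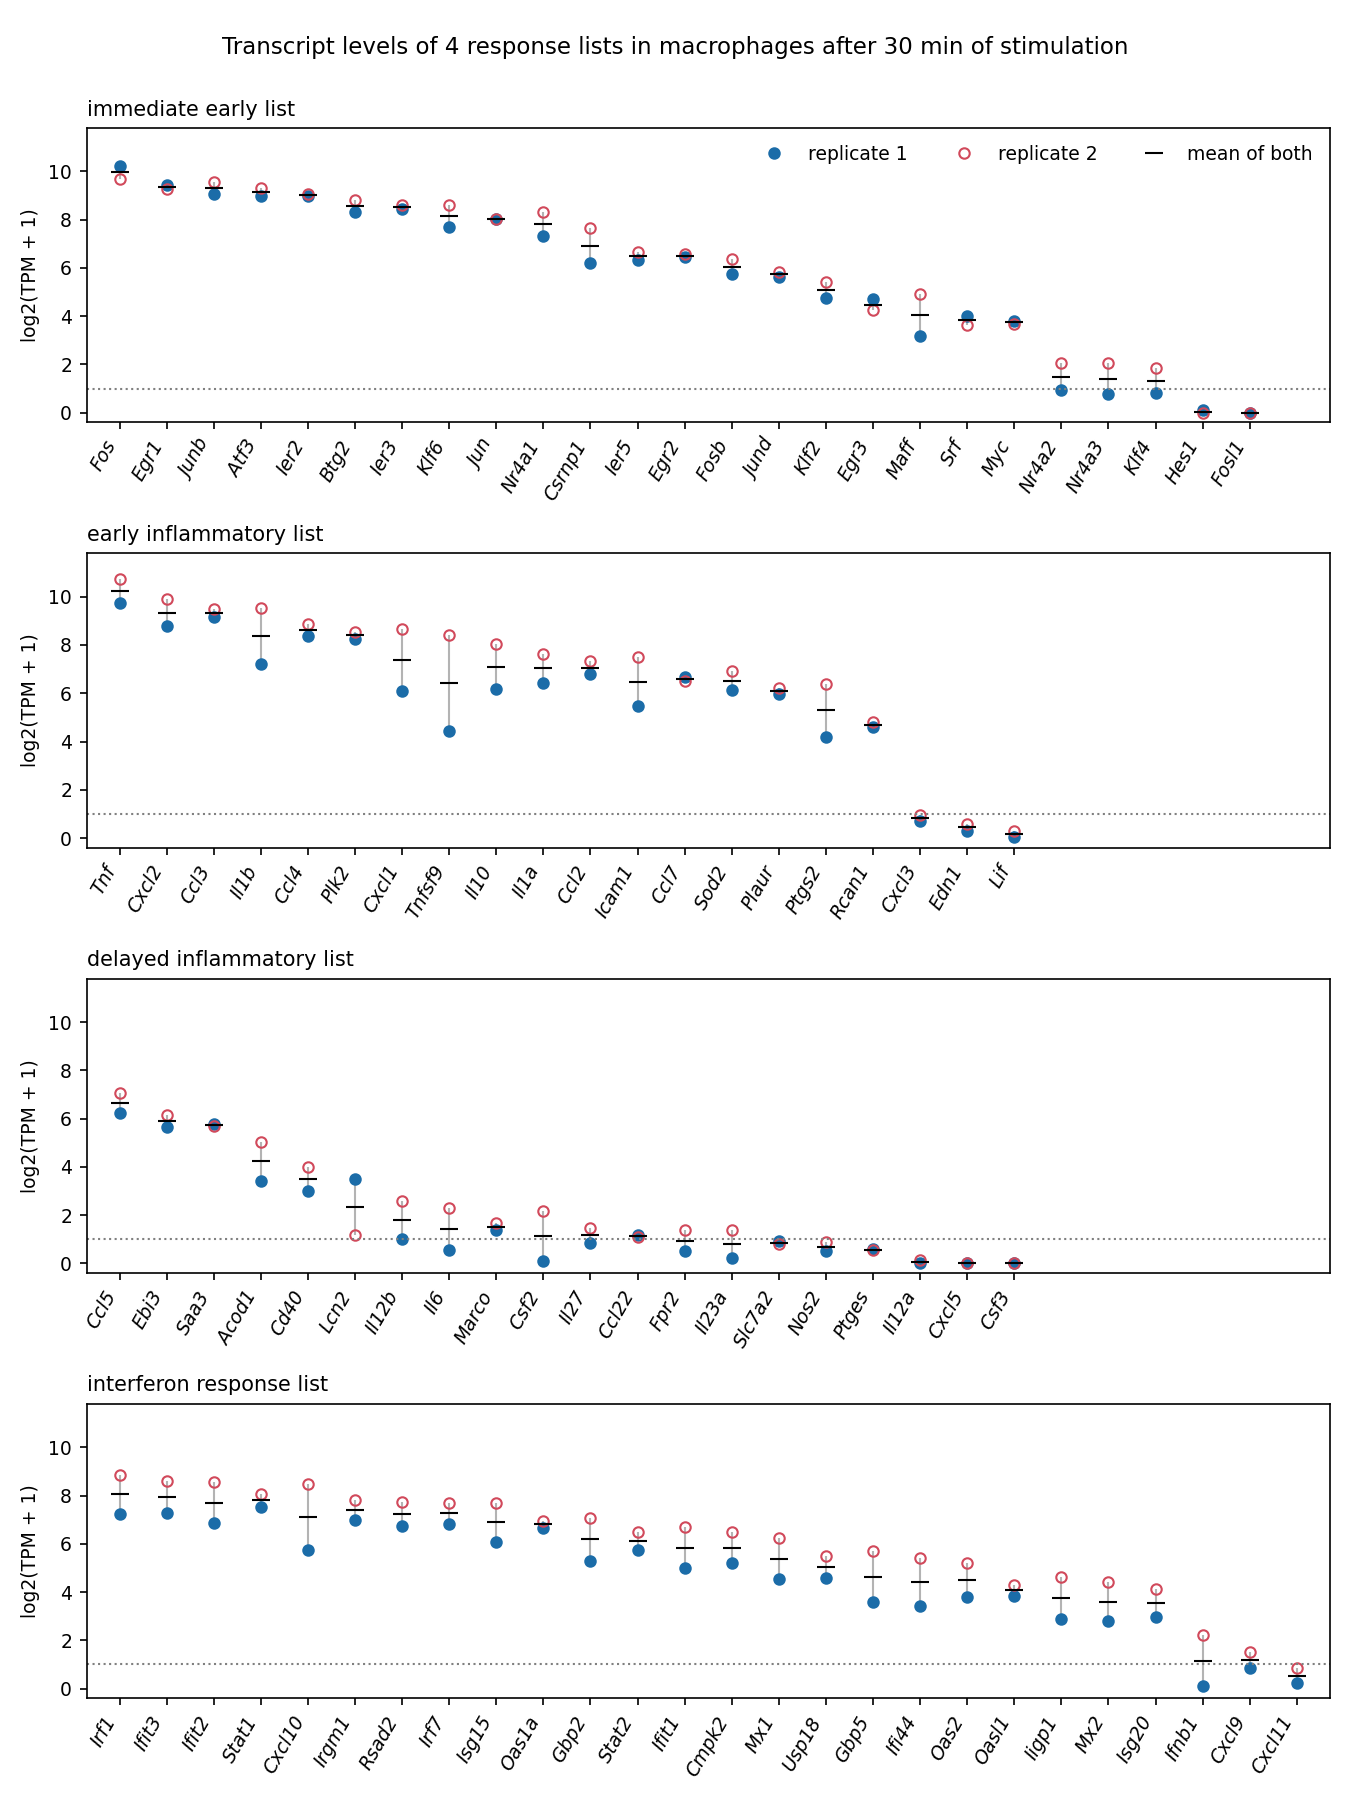
Level of each gene of the immediate early, early inflammatory, delayed inflammatory and interferon response lists as log2(TPM + 1), with filled circles for replicate 1, open circles for replicate 2, a short bar for their mean and a dotted line at 1 TPM. Most genes of the delayed list lie near or below that line, and every gene of the interferon list lies higher in replicate 2.

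The delayed list lay below each of the other 3. Its median of mean log2(TPM + 1) was lower than that of the early inflammatory list by 5.66 (two-sided permutation test over genes, p = 1e-04, adjusted p = 0.00028) and lower than that of the immediate early list by 5.35 (permutation p = 6e-05, adjusted p = 0.00028). The delayed list minus the interferon list gave -4.69 (permutation p = 0.00014, adjusted p = 0.00028). The immediate early, early inflammatory and interferon lists did not separate: early inflammatory minus interferon gave 0.98 (permutation p = 0.15, adjusted p = 0.22), immediate early minus interferon 0.66 (permutation p = 0.51, adjusted p = 0.60) and immediate early minus early inflammatory -0.31 (permutation p = 0.60, adjusted p = 0.60). With only members at 1 TPM or more on average, early inflammatory minus interferon was 1.21 with a permutation adjusted p = 0.027, against a range of 0.027 to 0.573 over its alternatives. These p-values are over genes, which are not independent replicates, and are adjusted over the 6 pairs of lists.

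The receptor chain for lipid A was expressed. Of 25 TLR4 pathway genes, 24 were at 1 TPM or more in both libraries, with a median of 26.0 ± 2.74 TPM. Tlr4 (ENSMUSG00000039005.13, chromosome 4, 66827584 to 66930284) was at 54.5 ± 7.96 TPM, Ly96, which encodes its partner MD-2, at 39.0 ± 15.9 TPM, and the adaptor gene Myd88 at 60.9 ± 9.04 TPM. The co-receptor gene Cd14 (ENSMUSG00000051439.7, chromosome 18, 36725067 to 36726798) was higher, at 684 ± 345 TPM. All 5 NF-kB subunit genes were at 10 TPM or more in both libraries, with Rela at 60.3 ± 11.1 TPM and Nfkb1 at 58.1 ± 9.41 TPM. Of 21 other pattern receptor genes, 19 were at 1 TPM or more in both libraries, with a median of 35.8 ± 14.6 TPM. The beta-glucan receptor gene Clec7a led them at 607 ± 110 TPM, with Tlr13 at 210 and 180 TPM, Tlr7 at 141 and 194 TPM and Tlr8 at 162 and 127 TPM. Tlr2, named after its values were seen, was at 71.6 and 199.7 TPM, so the order of these receptors differed between the libraries, while Tlr11 and Tlr12 were below 1 TPM in both.

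Genes of alternative activation, the state that interleukin 4 sets up, were divided. Of 10, 5 were below 1 TPM in both libraries and 3 at 10 TPM or more, and the list median was 1.01 ± 0.19 TPM, with 0 counts for Retnla and Ccl17 and 0 and 2 for Arg1. The receptor gene Il4ra was at 50.4 ± 2.04 TPM, the lectin gene Clec10a at 48.5 ± 3.88 TPM and Chil3, which encodes a chitinase-like protein, at 17.6 ± 4.65 TPM. All 17 glycolysis genes and all 14 housekeeping genes were at 1 TPM or more in both libraries, with medians of 37.1 ± 4.78 and 363 ± 47.9 TPM, and Gapdh was at 1509 ± 21.9 TPM. Of 16 cholesterol and lipid genes, 15 were at 1 TPM or more, with a median of 48.5 ± 7.39 TPM. The lipase gene Lpl was at 1099 and 547 TPM and the fatty acid receptor gene Cd36 at 738 and 182 TPM. Of 23 cell cycle genes, 21 were at 1 TPM or more in both libraries but 5 reached 10 TPM, with a median of 6.30 ± 2.88 TPM and the replication clamp gene Pcna highest at 306 ± 98.8 TPM. The 13 mitochondrially encoded genes took 1.22% and 1.84% of the counts, and together with 6 copies on chromosome 1 that share their sequence 2.19% and 2.77%.

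The 2 libraries ranked genes alike but differed in level well beyond counting error. Across 11106 genes at a mean of 1 TPM or more, log2(TPM + 1) had a Pearson correlation of 0.970 and a Spearman correlation of 0.969. The SD of the log2 ratio was 0.50, 82.9% of these genes lay within 1.5-fold, and 4.94% lay beyond 2-fold. The biological coefficient of variation from edgeR was 0.250. Of 12266 genes tested by an exact binomial test, 7788 differed between the libraries by more than sampling noise, 3944 higher and 3844 lower in replicate 2. Scaled by total counts in place of TMM, 7738 differed, 5255 higher and 2483 lower. Beyond 2-fold were 979 genes, 605 higher and 374 lower in replicate 2. This test compares these 2 libraries and no conditions, and its calls have no replicate behind them. In the counts by gene list that follow, higher and lower refer to TMM-scaled counts, and TPM can point the other way. Gapdh, for instance, was called lower in replicate 2 while its TPM was 1493 and 1524.

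**Figure D2:**
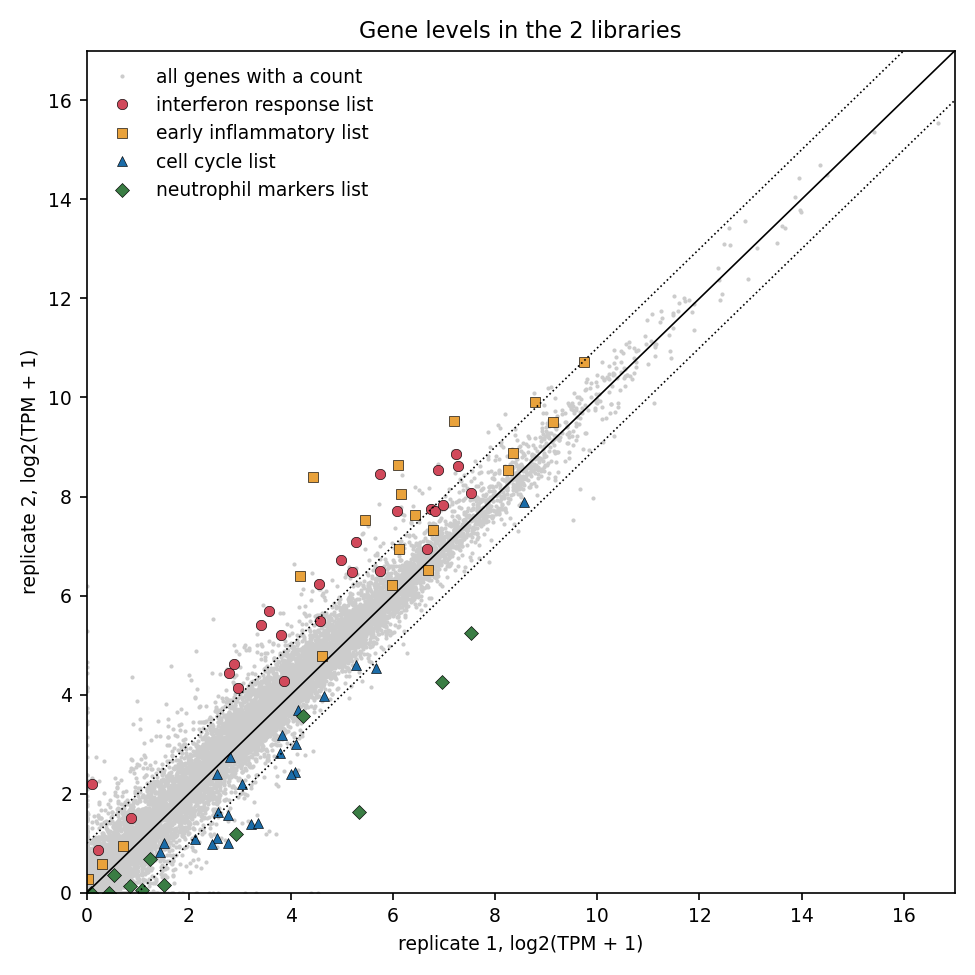
Level of every gene with a count in replicate 2 against replicate 1, both as log2(TPM + 1), with a solid line of equality, dotted lines at 2-fold, and symbols for 4 of the gene lists. Interferon response and early inflammatory genes lie mainly above the line, whereas cell cycle and neutrophil genes lie below it.

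Interferon response genes stood higher in replicate 2 as a group. All 24 that could be tested were higher in replicate 2 beyond sampling noise, 16 of them by more than 2-fold, including Cxcl10 at 52.8 and 352 TPM, Ifit1 at 30.6 and 104 TPM, Isg15 at 66.8 and 208 TPM and Irf1 at 150 and 464 TPM. Of 19 early inflammatory genes tested, 14 were higher and 1 was lower in replicate 2, with 9 more than 2-fold higher. Il1b was at 146 and 734 TPM, Cxcl1 at 67.3 and 399 TPM, Il10 at 70.3 and 265 TPM, Ptgs2 at 17.1 and 83.6 TPM and Tnf at 855 and 1691 TPM. Of 23 immediate early genes tested, 15 were higher and 6 lower in replicate 2, and Fos was lower, at 1211 and 822 TPM. Of 28 signal feedback genes, 19 were higher and 3 lower, with Nfkbia at 545 and 1178 TPM and Tnfaip3 at 147 and 356 TPM. Of 15 delayed inflammatory genes 9 were higher and 3 lower, of 20 other pattern receptor genes 14 were higher and 2 lower, and of 25 TLR4 pathway genes 15 were higher and 5 lower. All 5 NF-kB subunit genes were higher in replicate 2, Rel by more than 2-fold.

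Cell cycle and neutrophil genes went the other way. Of 23 cell cycle genes, 22 were lower in replicate 2 and 16 by more than 2-fold, with Pcna at 376 and 236 TPM, Cdk1 at 49.6 and 22.2 TPM and Mcm6 at 37.7 and 23.2 TPM. Of 7 neutrophil markers tested, 5 were lower and 4 of them by more than 2-fold, and of 4 megakaryocyte genes 3 were lower. Of 30 macrophage identity genes, 10 were higher and 17 lower, none by more than 2-fold. Lower in replicate 2 were also 19 of 23 lysosome genes and 10 of 14 housekeeping genes, against 3 higher in each list. In TMM-normalized CPM, however, random lists matched on expression were shifted down too. Their median log2 ratio was -0.158 for lysosome, -0.111 for housekeeping and -0.112 for macrophage identity genes. The lists themselves had -0.271, -0.284 and -0.186, at percentiles 5.17, 2.92 and 13 of the matched lists. These counts alone therefore do not set the lists apart from other genes of like expression. Of 17 glycolysis genes 6 were higher and 7 lower, of 15 cholesterol and lipid genes 10 were higher and 5 lower, and of 13 mitochondrially encoded genes 10 were higher and 3 lower. The direction of a mitochondrial gene can depend on how reads were split with the copies on chromosome 1. mt-Co3 was at 234 and 101 TPM, but at 1400 and 1809 TPM in the second quantification. mt-Nd3 was lower in replicate 2 in both, at 448 and 261 TPM and at 1356 and 1108 TPM. Adjusted over the list alone, the counts were equal to those given except for 4 signal feedback genes lower, 16 TLR4 pathway genes higher and 6 neutrophil markers lower.

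The shift of each list was then set against random lists of the same size matched on expression, since the median log2 ratio of all genes was itself 0.09 in TPM and -0.01 with TMM scaling. The excess of the list median over the matched lists was 1.32 for interferon response, 0.65 for early inflammatory, 0.51 for other pattern receptors, 0.40 for delayed inflammatory, 0.29 for immediate early and 0.27 for signal feedback genes. It was 0.39 for mitochondrially encoded genes and 0.30 for cholesterol and lipid genes, where Lpl and Cd36 nonetheless stood lower in replicate 2. It was -1.09 for cell cycle, -0.93 for neutrophil, -0.48 for dendritic cell, -0.44 for monocyte, -0.36 for megakaryocyte, -0.29 for lysosome and -0.22 for housekeeping genes. The pseudocount of 1 TPM shrinks the ratios of low genes, and the order of the lists depends on it: in TMM-normalized CPM the excess was -2.81 for neutrophil, -1.46 for megakaryocyte, -1.28 for cell cycle, -1.10 for dendritic cell, -0.74 for T cell, 0.75 for delayed inflammatory, 1.01 for early inflammatory and 1.52 for interferon response genes. With a pseudocount of 0.1 TPM it was -2.37 for neutrophil, -1.06 for megakaryocyte and -1.02 for dendritic cell genes. Of the 28 lists, 8 lay above and 10 below the central 95% of matched lists. Independent genes would put 1.4 lists outside it, but genes of a list move together, so that this number is no chance expectation here. The osteoclast, T cell and B cell lists were the others below it, with an excess of -0.19, -0.08 and -0.01. The T cell list (median 0.11 and 0.02 TPM) and the B cell list (0.03 and 0.02 TPM) lay near the floor. Only 2 members of each could be tested. TLR4 pathway genes, with an excess of 0.15, NF-kB subunits, with 0.28, and macrophage identity genes, with -0.15, lay inside the central 95%. Glycolysis (0.02), alternative activation (-0.01), stromal (-0.01) and endothelial genes (0.14) lay inside it as well, as did the NK cell, erythroid and mast and basophil lists, whose median shift was 0. The lysosome, housekeeping, monocyte, osteoclast and B cell lists lay inside it with TMM or DESeq2 scaling, and the T cell list with TMM scaling, while the TLR4 pathway list lay above it with both.

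**Figure D3:**
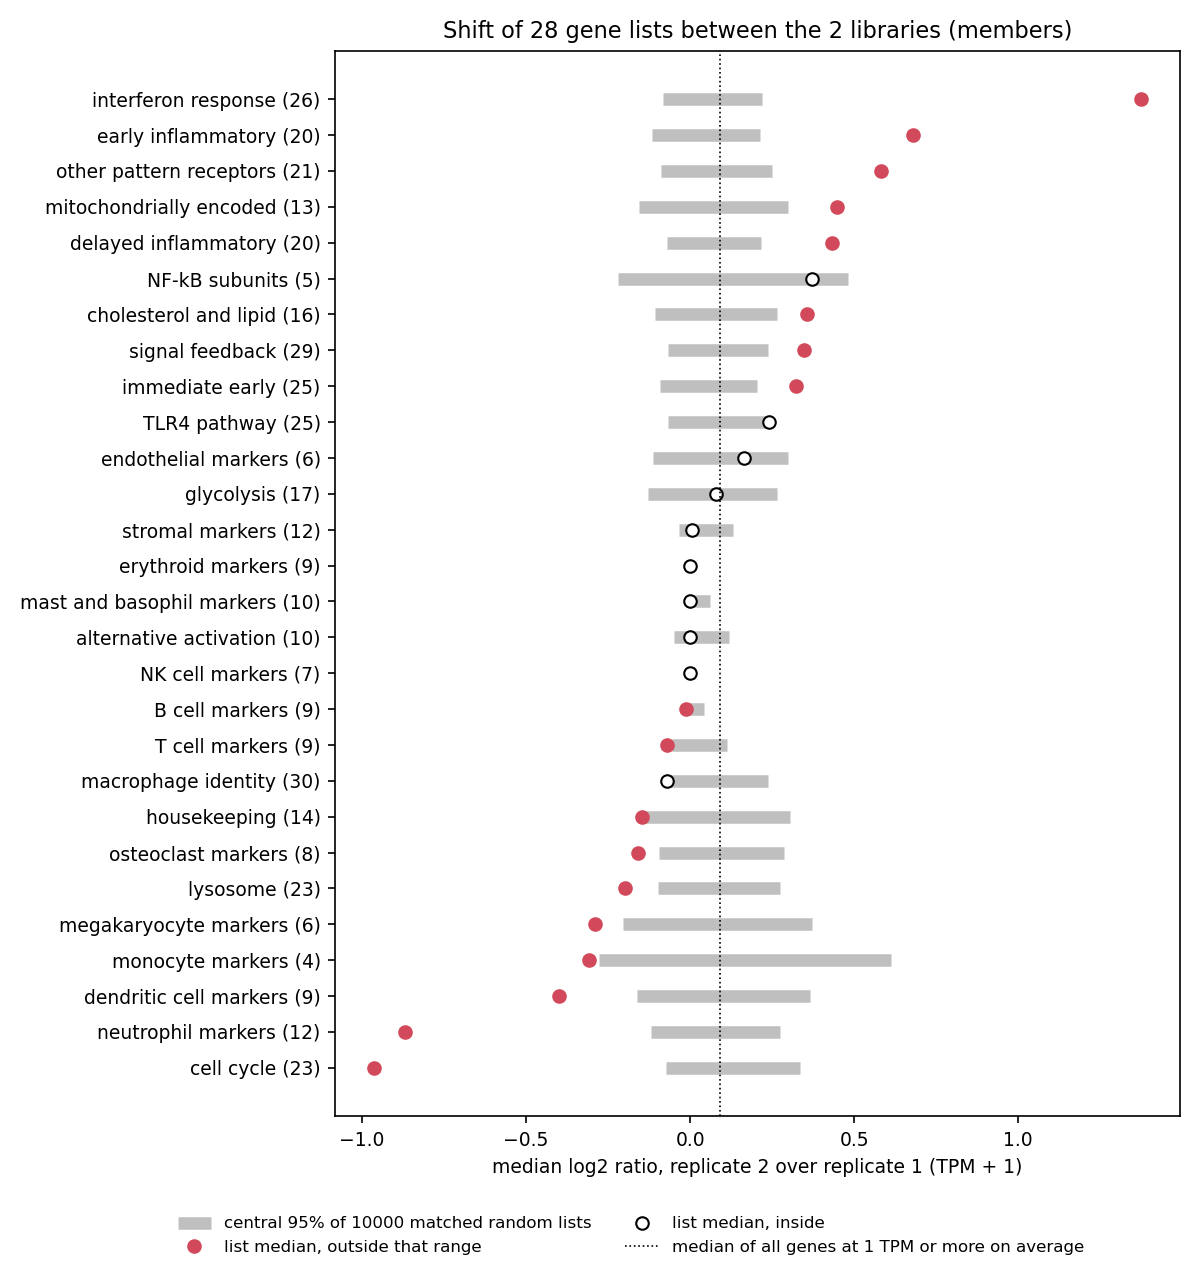
Median log2 ratio of replicate 2 to replicate 1 (TPM + 1) for each of the 28 gene lists, with grey bars for the central 95% of 10000 matched random lists, filled circles outside and open circles inside that range, and a dotted line at the median of all genes. Interferon response lies farthest to the right at 1.38 and cell cycle farthest to the left at -0.96.

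The 10 genes with the largest ratio between the libraries came from 6792 eligible genes, and 7 of them were higher in replicate 2. They included Tnfsf9, a T cell co-stimulatory ligand, at 20.5 and 336 TPM (16.3-fold), Mir155hg, the host transcript of the microRNA miR-155, at 0.84 and 19.4 TPM (23.1-fold), and Clec4e, the receptor Mincle, at 15.6 and 98.9 TPM (6.33-fold). Ifit1bl1 was at 3.41 and 28.4 TPM, Cxcl10 was 6.68-fold higher, and the unconfirmed transcripts AC167363.2 and Gm42793 were at 4.56 and 45.0 TPM and at 2.16 and 23.1 TPM. Lower in replicate 2 were the neutrophil granule gene Ngp, at 39.2 and 2.09 TPM (18.8-fold), S100a8 (6.84-fold) and the antisense transcript Gm37401, at 22.1 and 0 TPM. Gm37401 was at 0.36 TPM on average in the second quantification. Each of these genes that could be tested differed beyond sampling noise. Their choice by largest ratio made this all but certain, so it adds no support. Gm37401 was not tested.

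Most early response genes were represented by a single dominant transcript. In the immediate early, signal feedback and early inflammatory lists, 58 genes were at 10 TPM or more on average. In 44 of them the leading transcript took 80% or more of the gene's TPM in both libraries. These 44 include the 15 genes with a single annotated transcript, whose share was fixed beforehand. In 7 genes a second transcript took 20% or more in both. For Dusp1, transcript Dusp1-206 took 54.3% ± 6.04 (SD, n = 2) and Dusp1-202 took 40.0% ± 2.07. In the second quantification their means were 42.7% and 49.9%, with the order kept in replicate 1 (49.0% and 47.3%) and turned round in replicate 2 (36.4% and 52.5%). For Atf3, Atf3-201 took 76.9% ± 3.68 and the noncoding Atf3-202 took 23.1% ± 3.59. For Csrnp1, Csrnp1-201 took 60.7% ± 0.92 and Csrnp1-205 took 37.8% ± 0.19. For Egr3, the protein-coding transcript ENSMUST00000225200.1 took 54.7% ± 5.27 and ENSMUST00000223747.1, annotated as a retained intron, took 39.8% ± 1.48, against 61.6% and 21.4% in the second quantification. Tnip1-205 took 52.3% ± 5.75 of Tnip1 and Tnip1-202 took 23.5% ± 3.05. The leading transcript of Sod2 was the noncoding Sod2-207 at 32.6% ± 14.4, with 27.8% ± 7.16 for Sod2-201, and their order differed between the libraries. In the second quantification Sod2-207 led in both libraries, at 43.0% and 28.3% against 18.4% and 23.2%. Myc-201 and Myc-205 took 34.3% ± 2.39 each, and as they have the same span and length their reads were not told apart.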

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

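These entries lie outside the gene comparisons and their counts were above the limit that 0 counts allow; no explanation was tested. Reads of the sequencing control phiX numbered 33703 in replicate 1 and 36237 in replicate 2. In the second quantification the microRNA gene Mir6236 (ENSMUSG00000098973.1, chromosome 9, 110281287 to 110281409) had 67123 estimated counts in replicate 1 and 97324 in replicate 2, or 14.2% and 12.4% of TPM there, and 0 counts in the main gene table. All microRNA genes together took 20.1% and 17.1% of TPM in the second quantification.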

How the results depend on the processing

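Chosen after seeing the data were the alternatives for list shifts on members at 1 TPM or more, rescaled TPM, protein-coding transcripts, the second quantification and matching on GC content and length; the others were set before. The number of genes detected stayed between 8174 and 12253 under all 8 alternatives, and the number beyond sampling noise between 7738 and 8209 under all 3. The correlation was 0.952 with a pseudocount of 0.1 TPM and 0.986 without a filter, and the biological coefficient of variation 0.281 without a filter, where more low genes enter. The 20 genes of highest mean TPM, a set picked anew, held 33.0% of TPM. That set includes mt-Atp8, rank 2 by TPM but 356 by counts, and the cause of the higher share was not tested. Leaving out either replicate, detected genes ranged from 10967 to 11150, the top 20 share from 23.4% to 28.7%, and every pair of lists kept its side of the threshold; immediate early minus early inflammatory, not past the threshold in any setting, went from -1.01 to 0.08 and was 0.51 in TMM-normalized CPM. Immediate early minus interferon went from 0.08 without replicate 1 to 1.13 without replicate 2. Early inflammatory minus interferon passed only with members at 1 TPM or more (1.21).

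List shifts held their side of the central 95% in 182 of 207 comparisons of a list with an alternative, and no list outside it turned to the other side. In TMM-normalized CPM the excess was 0.22 for TLR4 pathway (now outside), and inside for lysosome (-0.11), housekeeping (-0.17), T cell (-0.74), B cell (-0.13), monocyte (-0.54) and osteoclast (-0.29). With DESeq2 size factors it was 0.22 for TLR4 pathway, -0.11 for lysosome, -0.17 for housekeeping, -0.13 for B cell, -0.54 for monocyte and -0.29 for osteoclast. With a pseudocount of 0.1 TPM TLR4 pathway lay outside (0.18) and osteoclast inside (-0.32). Inside were also T cell (-0.089) and B cell (-0.018) in rescaled TPM, B cell (-0.014) and osteoclast (0.00) with protein-coding transcripts, and T cell (-0.093) in the second quantification, where TLR4 pathway lay outside (0.23). Matched on GC content and length, TLR4 pathway lay outside (0.17), and housekeeping (-0.18), dendritic cell (-0.48) and osteoclast (-0.37) inside. The cause was not tested. The early inflammatory, delayed inflammatory, interferon and immediate early lists stayed above the central 95% under all 8 alternatives. So did the signal feedback, other pattern receptor, and cholesterol and lipid lists. The cell cycle and neutrophil lists stayed below it under all 8. The mitochondrially encoded list stayed above it and the megakaryocyte list below it under each alternative that gave them a value. Lists with fewer than 3 usable members gave no value under some settings: B, T and NK cell, erythroid, mast, megakaryocyte, stromal and endothelial with members at 1 TPM or more or matched on GC content, and mitochondrially encoded in rescaled TPM.

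Of 145 named gene levels, 43 moved by more than the SD between libraries in the second quantification, where 129 were lower with a median ratio of 0.846 and microRNA genes took 20.1% and 17.1% of TPM, which lowers all other TPM alike, and 28 did so with the posterior mean. The leading transcript share moved in 5 of 7 genes in the second quantification. No paired analysis was possible because both libraries belong to 1 group. Depth limits genes near the floor, which hold most of the marker lists of other cells.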

Other observations

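Apart from ribosomal RNA, long noncoding, antisense and unconfirmed transcripts made up a small part of both libraries. Long intergenic noncoding RNAs took 0.235% of the counts of replicate 1 and 0.420% of those of replicate 2, a ratio of 1.79, with 106 of them at 1 TPM or more in both libraries. Antisense transcripts took 0.0484% and 0.0693% (ratio 1.43), and transcripts still to be experimentally supported took 0.0210% and 0.0420% (ratio 2.00). Protein-coding genes took 87.1% and 92.7%, while the ribosomal RNA class took 10.9% and 5.05%. Small nucleolar RNAs (ratio 0.70, on 159 and 153 counts), miscellaneous RNAs (0.89, on 532 and 649 counts) and mitochondrial ribosomal RNA (0.96) also had ratios below 1. In TPM, small nucleolar RNAs (134 and 184) and miscellaneous RNAs (302 and 329) went the other way. All classes in this paragraph were singled out after their values were seen.

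The tests in this part on protein-coding transcripts, on GC content and length, on macrophage identity and on the rank of mt-Atp8 were chosen after the result was seen; those on genomic span, on a second list of neutrophil genes and on shared sequence were written before theirs.

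The early inflammatory and interferon response lists stood higher in replicate 2. Transcripts annotated as noncoding, such as retained introns, are argued against as the source. With protein-coding transcripts only, the smaller excess of the 2 lists was 0.74, against 0.65 over all transcripts. Reads of unspliced RNA that were assigned to protein-coding transcripts were not separated by this test. GC content and length are argued against as well. Over the members at 1 TPM or more (17 early inflammatory genes), the smaller excess was 0.91 against lists matched on both. It was 0.96 against lists matched on expression alone. A longer effective time of stimulation in replicate 2 may be a cause, and would let long genes catch up, but across 92 response genes the log2 ratio followed genomic span with a Spearman rho of 0.084 (permutation p = 0.43, bootstrap 95% interval -0.13 to 0.30; genes are not independent replicates), which decides nothing. A stronger ligand response, a different interferon state before treatment, and culture or library differences stay open, and with no untreated samples none of them was tested.

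Neutrophil markers stood lower in replicate 2, with 10 of 10 members at 10 counts or more lower and 5 beyond sampling noise. Cells of the neutrophil lineage in replicate 1 are a candidate explanation. In a second list of 22 genes, 11 had 10 counts or more in at least 1 library. Their excess was -0.46, below all but 0.155% of matched lists. The matched genes faced no such limit, so the percentile does not compare like with like. Pglyrp1 (16 and 0 counts), Fcnb (18 and 2), Ctsg (13 and 0) and Itgb2l (17 and 2) met the limit in replicate 1 alone. Most of these 11 lay near the floor, however, and the most abundant, Ifitm6 at 6.31 and 18.1 TPM and Padi4 at 3.39 and 5.21 TPM, were higher in replicate 2: 9 of the 11 were lower there, 2 lower and 2 higher beyond sampling noise, and how many of the 22 genes macrophages also express was not tested. A less mature or mixed culture in replicate 1 might also leave such transcripts. The medians of the cell cycle (excess -1.09), dendritic cell (-0.48), monocyte (-0.44) and megakaryocyte lists (-0.36) were lower in replicate 2 too. However, the monocyte list lay inside the central 95% with TMM or DESeq2 scaling, and 1 of its 4 genes was higher beyond sampling noise. The dendritic cell list, over 3 members, lay inside when matched on GC content and length. Of 6 megakaryocyte genes, 4 were below 1 TPM in both libraries, and only Pf4 (962 and 250 TPM) reached 100 TPM. A less mature culture in replicate 1 would put the macrophage identity list higher in replicate 2. Its excess of -0.15 had the opposite sign but lay inside the central 95%. The list thus did not decide it, and the 2 explanations stay open. The levels of S100a9 (183 and 37.1 TPM) and S100a8 (124 and 18.1 TPM) are those of the most abundant markers, and no sort or gate is named in the labels.

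The high TPM of mt-Atp8 and of pseudogenes on chromosome 1 may be a matter of read assignment and length. Of the 31-base words of 6 pseudogenes between 24612407 and 24616197, 99.5% occur in annotated mitochondrial transcripts, and the split between copies differed by method: Gm28437 was at 11741 and 8852 TPM with mt-Co3 at 234 and 101 TPM, against 7552 and 5212 TPM with 1400 and 1809 TPM in the second quantification. Gm10925 went from 8917 and 8245 TPM to a mean of 126 TPM there, while mt-Atp6 went from 72.1 and 184 TPM to 6493 and 6553 TPM. For mt-Atp8, rank 2 by TPM but 356 by counts, an effective length of 13.9 and 12.2 bases is a candidate cause. No biological explanation was tested, and expression of the nuclear copies was not separated from that of the mitochondrial genes.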
